A study of Mus musculus with 6 samples.

How the data were processed

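The series compared mouse E14Tg2A embryonic stem cells nucleofected with an antisense oligonucleotide labelled RC, the control, or with one against LINE1, with 3 libraries in each arm taken 48 h after delivery. Libraries were made with a directional mRNA kit from 1 ug of DNase-treated RNA of sorted fluorescent cells, per the labels' protocols.

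The authors deposited raw read counts per gene symbol and raw read counts per repeat name, with 1 column per library in each of 2 tables. Per the submitters' processing notes, TopHat2 2.0.9, HTSeq 0.6.1p1, R 3.3.0 and DESeq2 1.12.3 were used with the mm9 genome build. The strand setting of the counting, the annotation release, the repeat annotation and the treatment of reads that map to several places are not given in the sources used here. Reads shared between near-identical genes or repeat copies could therefore be lost, split or assigned at random, which bears on the Zscan4 family, other 2-cell-stage genes and all repeats. The gene table held 19467 symbols while 1217 names were listed for repeats, of which 86 had no read. Each entry names a gene or a repeat.

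Counts were analysed as deposited in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by edgeR's filterByExpr on the arms with its defaults (a minimum count of 10 and a minimum total of 15), library sizes were scaled by TMM, and the arms were compared with robust quasi-likelihood fits and F tests. The Benjamini-Hochberg adjustment ran over all 14725 genes kept, and a gene was called at an adjusted p under 0.05 with no fold minimum. Standard errors of log2 fold changes are the log2 fold change divided by the square root of F. Repeats were tested in the same way with library sizes and TMM factors taken from the gene table, so that a change across a whole family would not be scaled away, and 806 repeats were kept. Summed reads of the L1Md and MERVL repeats were expressed as CPM, counts scaled to the TMM-adjusted total of gene-assigned reads, and compared with a two-sided exact permutation test on log2 values over 20 assignments. A total of 23 gene lists was fixed before the data were examined, of which 22 had at least 5 tested members. The mitochondrially encoded list had 0 genes in the table. Lists were tested with camera (preset correlation 0.01), with camera and an estimated correlation, and with fry, each adjusted over the 22 lists. With the preset correlation 12 lists passed, with an estimated correlation 0, and with fry 4, the 2-cell-stage, ribosomal protein, immediate early and germline lists, of which 0 passed by fry with the replicate block.

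The genes named in the text come from a rule set before the data were examined. It takes the 8 genes with the largest change in each direction among those called with a mean log2 CPM of at least 1 and no overlap of the arms, and up to 4 called members of each list by smallest p. It adds a fixed panel of Ncl, Trim28, Dux, Zscan4c, Zscan4d, Zfp352, Pou5f1, Nanog and Sox2, and among repeats the 5 largest called in each direction, every L1Md repeat, MERVL-int, MT2_Mm, IAPEz-int, GSAT_MM and the ribosomal RNA repeats.

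Both arms number their replicates 1 to 3, and no label says what a number shares. Deviations from the arm means over the 14725 genes correlated at 0.436, 0.659 and 0.394 between libraries of the same number, and from -0.475 to 0.220 between libraries of different numbers. Each same-number value was over 0.1, so the numbers were taken to pair the libraries. Control replicate 3 with LINE1 ASO replicate 1 (0.220) and control replicate 1 with LINE1 ASO replicate 3 (0.120) were over 0.1 too. This limit alone therefore does not set replicates 1 and 3 apart, although each library correlated most with the library of its own number. Fits with the replicate number as a block rest on this pairing. They are given where they changed a call or moved a count by over 1.5 times. The first principal component (59.3% of variance) separated the arms and the second (26.1%) replicate 2 of both arms. No libraries of 1 arm agreed within sampling noise, with chi-square values per degree of freedom from 9.01 to 37.8. TMM factors were 0.962 to 0.991 in the control arm and 1.02 to 1.04 in the LINE1 ASO arm, and the median log2 fold change of all genes was 0.01 with TMM, -0.01 with RLE factors and 0.09 with library totals.

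Alternatives were DESeq2 1.42.0, RLE factors, library totals, no count filter, a filter of 1 CPM in all libraries of 1 arm, the replicate block, a 2-fold minimum and leaving out each library. Repeats were also scaled by their own table and fitted in one table with the genes. Scaling, set test and left-out libraries were varied for the lists, and scale, pairing and left-out libraries for the summed repeats. Leaving out both replicate 2 libraries, and one table of genes and repeats with the replicate block, were added after the data were seen. Counts of 14725 genes were simulated with the means, dispersions and library sizes of this comparison. The gene test recovered 72 of 99 genes changed 2-fold (72.7%) and 94 of 98 changed 4-fold (95.9%). It also called 19 of 14393 unchanged genes. In this simulation false calls thus made up a larger share of all calls than the threshold on adjusted p aims at. The gene calls given here may therefore hold more false ones than that threshold implies. Gene length, GC content and transcript sequences came from the GENCODE M21 annotation, whose build differs from mm9, so no coordinates are given. A single gene model was found for 98.3% of symbols. The paper's own results, read lengths and the reads themselves were not used here.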

Results

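Messenger RNA was sequenced from E14Tg2A cells, a mouse embryonic stem cell line kept here in serum and leukaemia inhibitory factor. The cells received 5 nmol of an antisense oligonucleotide (ASO) carrying the red fluorophore Lissamine by nucleofection, a form of electroporation that brings nucleic acids into the nucleus. One arm received an ASO labelled RC, the control, and the other an ASO against LINE1, the long interspersed retrotransposon family. After 48 h, 300000 fluorescent cells were sorted per sample for RNA extraction, with 3 libraries in each arm. The control libraries held 19954026, 26868638 and 29092272 gene-assigned reads in replicates 1, 2 and 3, and the LINE1 ASO libraries 31704616, 29862338 and 26633433. A second table held 1576809, 1731794 and 2016922 repeat-assigned reads in the control libraries and 2442116, 1563826 and 1938165 in the LINE1 ASO libraries. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

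The first comparison asked whether reads of the targeted repeats differed between the arms. The 6 L1Md repeats, the evolutionarily young mouse LINE1 subfamilies, summed to 6534 ± 2255 CPM (counts scaled to library size) in the control arm and 5694 ± 2118 in the LINE1 ASO arm (SD, n = 3 each). The log2 ratio of -0.20 was smaller than the spread between libraries (two-sided exact permutation p = 0.5, where 3 against 3 libraries cannot go below 0.1). The control libraries stood at 7891, 3931 and 7780 CPM in replicates 1, 2 and 3, and the LINE1 ASO libraries at 7220, 3275 and 6586. Each LINE1 ASO library lay below the control library of its own number, by log2 ratios of -0.13, -0.26 and -0.24 (paired exact permutation p = 0.25, the smallest that 3 pairs can give). Fitted singly, L1Md_A had a log2 fold change of -0.25 ± 0.35 (SE), L1Md_T of -0.21 ± 0.41 and L1Md_Gf of -0.16 ± 0.46. L1Md_F stood at -0.07, L1Md_F2 at -0.09 and L1Md_F3 at 0.06, and L1Md_F moved to 0.012 when scaled by library totals or by the repeat table. None of the 6 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (lowest adjusted p = 0.903). Without LINE1 ASO replicate 2 the summed ratio turned to 0.044, without control replicate 2 it was -0.49, and without LINE1 ASO replicate 1 or 3 it was -0.43 or -0.34. It was nearer to 0 without control replicate 1, at -0.059, or control replicate 3, at -0.076. Fitting genes and repeats in one table with the replicate number as a block, chosen after seeing the data, gave adjusted p = 0.00154 for L1Md_A, 0.00284 for L1Md_T and 0.0192 for L1Md_Gf, each lower (edgeR quasi-likelihood with Benjamini-Hochberg adjustment). L1Md_A also passed, at -0.25, without both replicate 2 libraries, likewise chosen after seeing the data (adjusted p = 0.0192 by the same edgeR test with Benjamini-Hochberg adjustment), and its adjusted p over all alternatives went up to 0.984.

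The second comparison asked which genes responded to the LINE1 ASO. Large increases were found among weakly expressed genes and small decreases among abundant genes. Of 14725 genes tested, 726 rose and 173 fell. The genes that rose had a median log2 fold change of 1.36 at a median of 4.17 CPM, and those that fell a median of -0.36 at 142 CPM. Of the genes that rose, 39.4% were under 1 CPM in the control arm, against 12.3% of tested genes. Small changes are harder to call at low counts, so part of this contrast may come from the test, which was not examined. Gm4858 rose 44.9-fold, from 0.0906 ± 0.0335 to 4.43 ± 3.03 CPM (SD, n = 3 each). Dcc, the receptor for netrin, rose 24.6-fold from 0.155 CPM and Cacna1e, a voltage-gated calcium channel subunit, rose 19.5-fold from 0.289 CPM. 5330417C22Rik rose 21.1-fold from 0.534 CPM, Gm10696 19.5-fold from 0.411 CPM and Arhgef33 23.4-fold from 0.362 CPM. Among the genes with the largest decreases, Ntn1, which encodes the ligand of Dcc, fell to 0.579 of its control level and the laminin chain gene Lama1 to 0.552. Pcyt1b, an enzyme of phosphatidylcholine synthesis, went from 115 ± 8.91 to 59.8 ± 5.21 CPM, a log2 fold change of -0.95 ± 0.09 (SE, adjusted p = 0.00394 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Dock11 fell to 0.508 of control, the G protein subunit gene Gna14 to 0.516 and Calml4 to 0.505, with Vat1l and Ccdc141 at 0.560 and 0.570. A change of at least 2-fold was found for 495 of the genes that rose and 1 of those that fell. The arms did not overlap for 28.7% of genes, against 10% by chance. With the replicate number as a block, 2591 genes were higher and 2373 lower, including 897 of the 899 called without it. With library totals and no factors 980 genes were higher and 50 lower, and DESeq2 gave 1047 and 585. The number of calls varied with the library left out, from 899 to 171, 1519 and 162 without control replicates 1, 2 and 3. It was 299, 1123 and 277 without LINE1 ASO replicates 1, 2 and 3. Dcc did not pass without control replicate 3 (adjusted p = 0.0569), nor Gm10696 without it (0.0733) or control replicate 1 (0.0564), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The log2 fold changes without LINE1 ASO replicate 1 went from 5.49 to 4.76 for Gm4858, from 4.62 to 3.95 for Dcc and from 4.28 to 3.45 for Gm10696. Pcyt1b passed in all 6 of these fits, whereas Ntn1, Lama1, Dock11, Gna14, Calml4, Vat1l and Ccdc141 had adjusted p of 0.0675 to 0.130 without control replicate 1 and 0.0582 to 0.157 without control replicate 3 by the same edgeR test with Benjamini-Hochberg adjustment. Without LINE1 ASO replicate 3 the 7 had 0.0748 to 0.154, and without LINE1 ASO replicate 1 all but Lama1 had 0.0753 to 0.132. Vat1l also did not pass without control replicate 2 (0.0521), nor Ccdc141 without LINE1 ASO replicate 2 (0.0605). Principal components set replicate 2 of both arms apart. Without both of these libraries, a setting chosen after seeing the data, 3039 genes were called, including 889 of the 899.

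**Figure D1:**
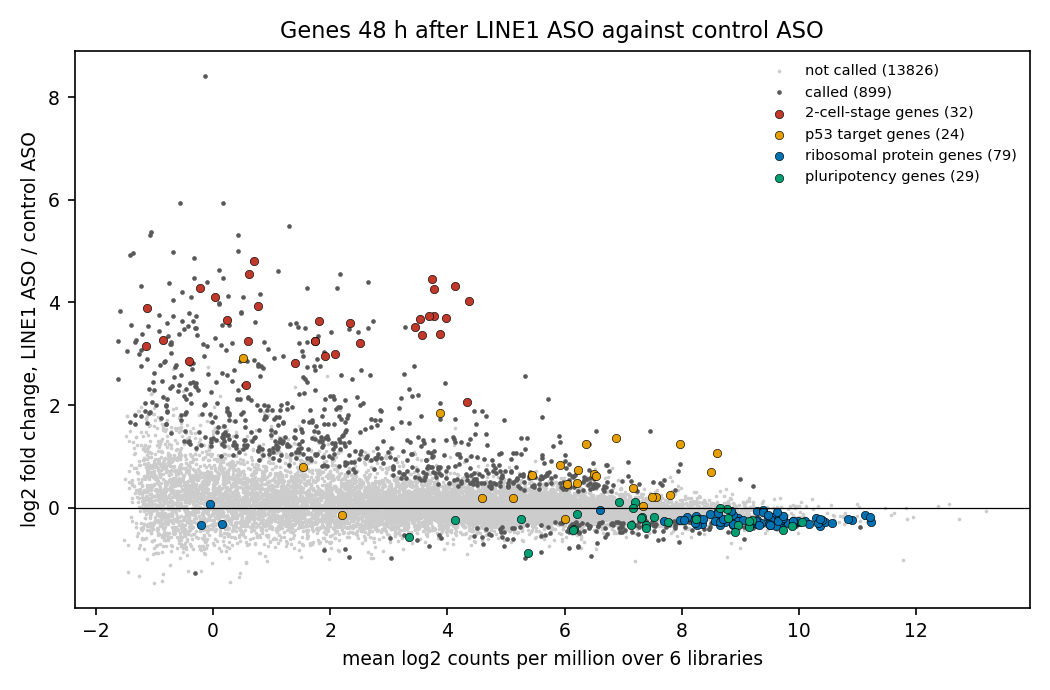
Log2 fold change of each of the 14725 tested genes (LINE1 ASO over control ASO, vertical axis) against its mean log2 CPM over the 6 libraries (horizontal axis), with 899 called genes in dark grey and 4 gene lists in colour. The 32 2-cell-stage genes lie above 2 on the log2 scale, while the 79 ribosomal protein genes sit at the abundant end with a median of -0.26.

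Genes transcribed in the 2-cell embryo rose most as a group. Of 32 tested members, 31 rose and 32 passed when adjusted over the list alone, with a median log2 fold change of 3.62, a 12.3-fold increase. Zscan4d, of the Zscan4 cluster that marks the 2-cell stage and the rare 2-cell-like cells of stem cell cultures, rose 20.1-fold, from 1.65 ± 0.305 to 32.7 ± 17.4 CPM (SD, n = 3 each). Zscan4c rose 16.4-fold, from 2.38 to 38.7 CPM. Dux, a homeobox transcription factor that activates 2-cell-stage genes, had 0, 6 and 1 reads in control replicates 1, 2 and 3 and 82, 39 and 34 in the LINE1 ASO replicates. Its log2 fold change was 4.10 ± 0.69 (SE, adjusted p = 0.0182 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Zfp352 rose 7.08-fold, Gm12794 21.9-fold, Gm2022 10.4-fold, Gm8300 10.3-fold and Gm2016 9.44-fold. In the LINE1 ASO libraries Zscan4d stood at 52.4 CPM in replicate 1, 19.2 in replicate 2 and 26.7 in replicate 3. The camera test with a preset correlation gave adjusted p = 5.28e-79 for the list, and adjusted p = 0.257 with an estimated correlation. Reads of these genes are shared between near-identical copies, so single-gene values are uncertain: 26 of the 31 members with a reference transcript had at least 5% of their 50-base sequences in other genes. Without control replicate 1, 20 members passed, and 18 without control replicate 3, and in these fits Dux had adjusted p = 0.0661 and 0.0960 (0.0511 without LINE1 ASO replicate 1) and Zfp352 0.0583 and 0.0569 by the same edgeR test with Benjamini-Hochberg adjustment. Without control replicate 2 the log2 fold change of Dux was 6.02, against 1 remaining control read.

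MERVL, the endogenous retrovirus whose long terminal repeats drive many 2-cell-stage transcripts, showed the largest difference among the repeat groups. Summed reads of MERVL-int and its terminal repeat MT2_Mm were 487 ± 66.8 CPM in the control arm and 2706 ± 1406 in the LINE1 ASO arm (SD, n = 3 each), 5.56 times higher. The arms did not overlap, and the two-sided exact permutation p = 0.1 was the smallest this design allows. Within replicate numbers 1, 2 and 3 the log2 ratios were 3.04, 1.89 and 2.14. MERVL-int had a log2 fold change of 2.51 ± 0.37 (SE) and MT2_Mm of 2.23 ± 0.31, each with adjusted p = 0.0659 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. DESeq2 with Benjamini-Hochberg adjustment gave adjusted p = 4.02e-10 for both, and over all alternatives the adjusted p ranged from 4.02e-10 to 0.466. Both passed in one table with the genes (adjusted p = 0.0107 and 0.00817, edgeR quasi-likelihood with Benjamini-Hochberg adjustment), without LINE1 ASO replicate 1 (0.0143 and 0.00629) and without LINE1 ASO replicate 2 (0.0487 and 0.0499).

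**Figure D2:**
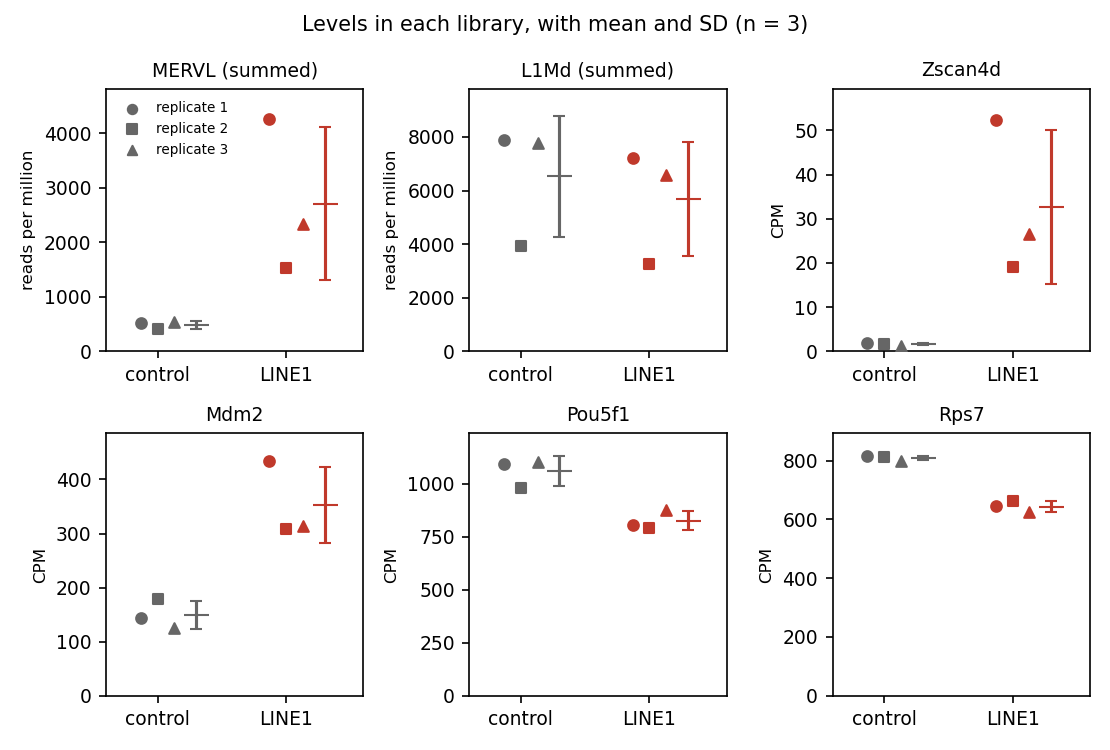
CPM of the summed MERVL and L1Md repeats and of 4 genes in each library, with replicates 1, 2 and 3 as circles, squares and triangles and the mean with its SD at the right of each arm (n = 3). MERVL, Zscan4d and Mdm2 lie higher in each LINE1 ASO library, Pou5f1 and Rps7 lower, and L1Md overlaps between the arms with replicate 2 lowest in both.

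No repeat passed the main test. Of 806 repeats tested, 0 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with or without the replicate block, and 53 had an unadjusted p under 0.05, of which 34 were higher. DESeq2 called 9, among them the endogenous retroviruses MMVL30-int, RLTR6_Mm, ORR1A3-int and MMERVK10C-int, which also passed in one table with the genes and were picked after their values were seen. They were 1.94, 2.84, 2.28 and 2.06 times their control levels. IAPEz-int, the internal part of the intracisternal A particle, had a log2 fold change of 0.24 ± 0.18 (SE), and the major satellite GSAT_MM of 1.22 ± 0.62. GSAT_MM stood at 0.57 without LINE1 ASO replicate 1 and passed in one table with the replicate block (adjusted p = 0.0393, edgeR quasi-likelihood with Benjamini-Hochberg adjustment; 0.0393 to 0.961 over all alternatives). IAPEz-int ranged from 0.0945 to 0.354 with 1 library left out. It passed without LINE1 ASO replicate 2 (adjusted p = 0.0127 by the same edgeR test with Benjamini-Hochberg adjustment, with 9.26e-04 to 0.961 over all alternatives). The lowest adjusted p came without both replicate 2 libraries, chosen after seeing the data. Ribosomal RNA repeats were lower without passing the main test, at -1.16 ± 0.41 for LSU-rRNA_Hsa and -1.24 ± 0.38 for SSU-rRNA_Hsa, and at -0.64 and -0.69 without control replicate 1. SSU-rRNA_Hsa was among the 9 that DESeq2 called (Benjamini-Hochberg adjusted p = 0.0253, with 0.0253 to 0.947 over all alternatives). The ribosomal precursor transcript Rn45s in the gene table, also picked after its values were seen, had a log2 fold change of -1.02 ± 0.33. It took 0.727%, 0.371% and 0.267% of gene-assigned reads in the control libraries and 0.274%, 0.224% and 0.217% in the LINE1 ASO libraries. Control replicate 1 thus stood highest, and control replicate 3 lay below LINE1 ASO replicate 1 by this share. The libraries came from an mRNA kit, so these reads need not follow the amount of ribosomal RNA, which was not tested. Without LINE1 ASO replicate 2, the library with the fewest repeat reads per gene read, 51 repeats were called, and 2 without LINE1 ASO replicate 1, MERVL-int and MT2_Mm. In simulated data of this design the repeat test recovered 15% of 20 repeats changed 2-fold and 85% of 20 changed 4-fold.

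A part of the targets of the tumour suppressor p53 rose. Of 24 tested, 8 rose, 16 passed when adjusted over the list alone and 22 had a log2 fold change above 0 (median 0.62). Mdm2, the ubiquitin ligase that degrades p53, went from 149 ± 26.6 to 353 ± 70.6 CPM (SD, n = 3 each), 2.36-fold. The death receptor gene Fas rose 7.55-fold, the p53 family gene Trp73 3.62-fold and the polo-like kinase gene Plk2 2.57-fold. The list had adjusted p = 1.38e-11 by camera with a preset correlation, against adjusted p = 0.282 with an estimated correlation and 0.0587 by fry. With the replicate block 18 members were higher, and the number was 1 without control replicate 1, 14 (with 1 lower) without control replicate 2, 3 without control replicate 3 and 4 without LINE1 ASO replicate 1 or 3. Mdm2 and Trp73 had adjusted p = 0.0549 and 0.0551 without control replicate 1, and Plk2 had 0.0754 without it and 0.0684 without control replicate 3 (edgeR quasi-likelihood, Benjamini-Hochberg adjustment).

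Germline and immediate early genes rose in smaller numbers. Of 17 germline genes 7 passed when adjusted over the list alone, and 4 rose over all genes. These 4 were Tex101, a germ cell surface protein gene (3.17-fold), the TFIID subunit gene Taf7l (2.47-fold), Dpep3 (5.07-fold) and the germ cell ADP/ATP carrier gene Slc25a31 (2.28-fold). Of 16 immediate early genes 5 passed when adjusted over the list alone, and 3 rose over all genes: Jun (2.06-fold), the antiproliferative gene Btg2 (2.37-fold, also a p53 target) and the matrix protein gene Ctgf (1.96-fold). By camera the germline list had adjusted p = 4.45e-04 and the immediate early list 0.0400 with a preset correlation, and adjusted p = 0.257 and 0.282 with an estimated correlation. The immediate early list did not pass with the replicate block (adjusted p = 0.138), without control replicate 1 (0.0769) or without LINE1 ASO replicate 2 (0.0907). With the block, which called 2591 of all 14725 genes higher and 2373 lower, 9 germline genes were higher and 1 lower. Of the immediate early genes 6 were higher and 3 lower. Members higher numbered 1 and 0 without control replicate 1 or without control replicate 3, 2 and 0 without LINE1 ASO replicate 1, and 2 and 1 without LINE1 ASO replicate 3. Tex101 passed in all 6 of these fits. The other named genes had adjusted p of 0.0550 to 0.125 without control replicate 1 and 0.0569 to 0.156 without control replicate 3 (edgeR quasi-likelihood, Benjamini-Hochberg adjustment). Without LINE1 ASO replicate 1 all of these but Taf7l had 0.0507 to 0.112, without LINE1 ASO replicate 3 all but Taf7l and Jun had 0.0772 to 0.120, and Ctgf had 0.0621 without control replicate 2. The log2 fold change of Dpep3 went from 2.34 to 3.14 without control replicate 2.

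A part of the genes of the cytosolic ribosome fell by a small amount. Of 79 ribosomal protein genes 21 fell, 60 passed when adjusted over the list alone, and 78 had a log2 fold change below 0 (median -0.26). Rps7 went from 809 ± 7.99 to 644 ± 19.4 CPM (SD, n = 3 each), a log2 fold change of -0.33 ± 0.06 (SE), with Rps13 at -0.33, Rpl27 at -0.35 and Rpl35a at -0.32. The list median was -0.28 with RLE factors and -0.18 with library totals. Other abundant genes were lower too: random sets matched on abundance, length and GC content had a median log2 fold change of -0.15 in the fit with the replicate block. By camera the list had adjusted p = 3.27e-22 with a preset correlation and adjusted p = 0.333 with an estimated correlation. With the replicate block 68 members were lower, and 41 without LINE1 ASO replicate 2, whereas 0 passed without control replicate 1, control replicate 3, LINE1 ASO replicate 1 or LINE1 ASO replicate 3. In these 4 fits the adjusted p of the named members was 0.0983 to 0.111, 0.0838 to 0.0976, 0.0621 to 0.0872 and 0.102 to 0.116 (edgeR quasi-likelihood, Benjamini-Hochberg adjustment).

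Among pluripotency genes 1 fell. Of 29 tested, 27 had a log2 fold change below 0 (median -0.26), of which 1 passed over all genes and when adjusted over the list alone: Pou5f1, which encodes Oct4, went from 1058 ± 70.2 to 824 ± 44.9 CPM (SD, n = 3 each). Its adjusted p was 0.0355 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and it did not pass without control replicate 1 (0.132), control replicate 3 (0.125), LINE1 ASO replicate 1 (0.110) or LINE1 ASO replicate 3 (0.0753). Without control replicate 2, 7 members were lower, and 2 without LINE1 ASO replicate 2. Sox2 had a log2 fold change of -0.20 ± 0.06 (SE) and Nanog of -0.22 ± 0.17, where Nanog ranged from -0.43 to -0.064 with 1 library left out. With the replicate block, which called 2373 of all 14725 genes lower, 20 members were lower. Sox2 was among them (adjusted p = 0.00378 by the same edgeR test with Benjamini-Hochberg adjustment) and Nanog was not (0.0579). By camera the list had adjusted p = 1.49e-06 with a preset correlation, against adjusted p = 0.282 with an estimated correlation and 0.0649 by fry. The nucleolar protein gene Ncl stood at -0.22 ± 0.07 and the corepressor gene Trim28 at -0.20 ± 0.11 (adjusted p = 0.109 and 0.325 by the same edgeR test). Both passed with the replicate block (Benjamini-Hochberg adjusted p = 5.59e-04 and 0.00483 by that test). The random sets matched to the ribosomal protein genes had a median of -0.15 with the block. The decreases of Ncl, Trim28 and Sox2 are therefore not set apart from that of other abundant genes.

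Of 6 further lists that were lower by the preset test, most members did not pass. Splits of the libraries that mix the arms called up to 10 lists by this test, against 12 for the real split. The ribosome biogenesis list had 1 of 60 members lower, Nop10 of the small nucleolar ribonucleoproteins, and 0 when adjusted over the list alone. The cholesterol synthesis list had 1 of 24 lower, Acat2, and 1 when adjusted over the list alone. The list of chromatin repressors of retrotransposons had 1 of 28 lower, the imprint regulator gene Zfp57, and 2 when adjusted over the list alone. The integrated stress and unfolded protein response list had 1 of 29 lower, the mitochondrial folate enzyme gene Mthfd2. Adjusted over the list alone it had 3 lower and 1 higher. The imprinted list had 0 of 23 past the test on either adjustment. The hypoxia and glycolysis list had 0 of 26 lower and 1 higher, Pfkfb4, a regulator of fructose 2,6-bisphosphate, which also passed when adjusted over the list alone. By camera with a preset correlation the lists had adjusted p = 0.00252, 0.00235, 0.0166, 0.00777, 0.0225 and 0.00438 in that order. With an estimated correlation the adjusted p was 0.710 for ribosome biogenesis, 0.257 for the stress response and 0.594 for the other 4. With the replicate block 26, 11, 11, 10, 10 and 16 members were lower in that order, and 3, 0, 3, 3, 4 and 2 higher. Of all 14725 genes the block had 2373 lower and 2591 higher. The ribosome biogenesis list did not pass without LINE1 ASO replicate 2 (0.185) or control replicate 1 (0.0638), nor did the chromatin repressors (0.134 and 0.0757). The hypoxia list did not pass without LINE1 ASO replicate 1 (0.0933) or control replicate 2 (0.281), nor the imprinted list without control replicate 1 (0.112), control replicate 2 (0.0531) or LINE1 ASO replicate 3 (0.0817). Without control replicate 2 the members lower numbered 10 for ribosome biogenesis, 7 for chromatin repressors, 3 for the stress response and 2 for cholesterol, and without LINE1 ASO replicate 2 they numbered 7 for the stress response, 3 for the imprinted list, 2 for ribosome biogenesis and 0 for chromatin repressors. For hypoxia the members higher and lower were 2 and 0 without control replicate 2, 0 and 1 without LINE1 ASO replicate 1 and 1 and 2 without LINE1 ASO replicate 2. The 5 named members had adjusted p of 0.116 to 0.152 without control replicate 1, 0.109 to 0.165 without control replicate 3 and 0.0744 to 0.124 without LINE1 ASO replicate 1 (edgeR quasi-likelihood, Benjamini-Hochberg adjustment). Without LINE1 ASO replicate 3 all but Zfp57 had 0.102 to 0.135, and Zfp57 had 0.0616 without LINE1 ASO replicate 2.

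Lists of lineage markers and of primed epiblast, cell cycle, interferon response, histone and heat shock genes did not pass as groups. Of 15 primed epiblast genes Wnt8a rose (2 when adjusted over the list alone), and of 12 mesoderm markers Tbx4 rose 5.49-fold (3 over the list alone). Of 17 primitive endoderm markers Pdgfra and Cubn rose and Lama1 fell (2 and 2 over the list alone). Of 18 trophectoderm markers Krt7 rose and Bmp4 fell (2 and 1), and of 14 fibroblast markers Col6a1 rose and Acta2 fell (3 and 1). Of 7 neuroectoderm markers and 30 cell cycle genes 0 passed on either adjustment without the replicate block. Of 22 interferon response genes Mx2 and Cxcl10 rose, as they did over the list alone, of 17 histone genes Hist1h2bc, Hist1h4i and Hist1h1c, again the same number over the list alone, and of 12 heat shock genes Hspa1a and Hspa1b (3 higher and 1 lower over the list alone). With the replicate block the members higher and lower were 5 and 2 for primed epiblast, 4 and 1 for mesoderm, 3 and 4 for primitive endoderm, 5 and 3 for trophectoderm and 5 and 3 for fibroblast. They were 1 and 2 for neuroectoderm, 3 and 11 for the cell cycle, 2 and 5 for interferon, 4 and 1 for histones and 3 and 3 for heat shock. Of all 14725 genes the block had 2591 higher and 2373 lower, so several of these counts lie near the share of all genes. These 10 lists had camera adjusted p from 0.0995 for mesoderm to 0.602 for trophectoderm. The interferon list had a median log2 fold change of -0.14 and a mean of 0.10 with a test direction of lower, and primitive endoderm a median of 0.0055 (-0.014 with RLE factors) and a mean of 0.15 with a test direction of lower. Without LINE1 ASO replicate 3 the mesoderm list passed at adjusted p = 0.0126 and the cell cycle list at 0.0262, the latter also without control replicate 2 at 0.0148 and with no count filter at 0.0145. The log2 fold change of Mx2 went from 2.75 to 3.37 without control replicate 2. Without control replicate 2 the members higher and lower were 0 and 2 for primed epiblast, 1 and 1 for primitive endoderm, 3 and 0 for fibroblast, 1 and 0 for neuroectoderm and 2 and 2 for interferon. With LINE1 ASO replicate 2 left out they were 0 and 0 for primed epiblast and trophectoderm, 2 and 3 for primitive endoderm, 1 and 1 for mesoderm, 2 and 0 for fibroblast, 0 and 1 for neuroectoderm and 2 and 1 for interferon. Tbx4 passed in all 6 fits that left out 1 library. The other named members had adjusted p of 0.0675 to 0.149 without control replicate 1 and 0.0791 to 0.190 without control replicate 3 (edgeR quasi-likelihood, Benjamini-Hochberg adjustment). All of these but Hist1h2bc and Lama1 had 0.0511 to 0.154 without LINE1 ASO replicate 1, and all but Hist1h2bc had 0.0524 to 0.172 without LINE1 ASO replicate 3. Without control replicate 2, Wnt8a, Cubn, Acta2 and Hist1h1c had 0.0704, 0.0609, 0.0589 and 0.0640, and without LINE1 ASO replicate 2, Wnt8a, Krt7, Bmp4, Acta2 and Hspa1b had 0.0898, 0.0598, 0.0548, 0.0549 and 0.0520.

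**Figure D3:**
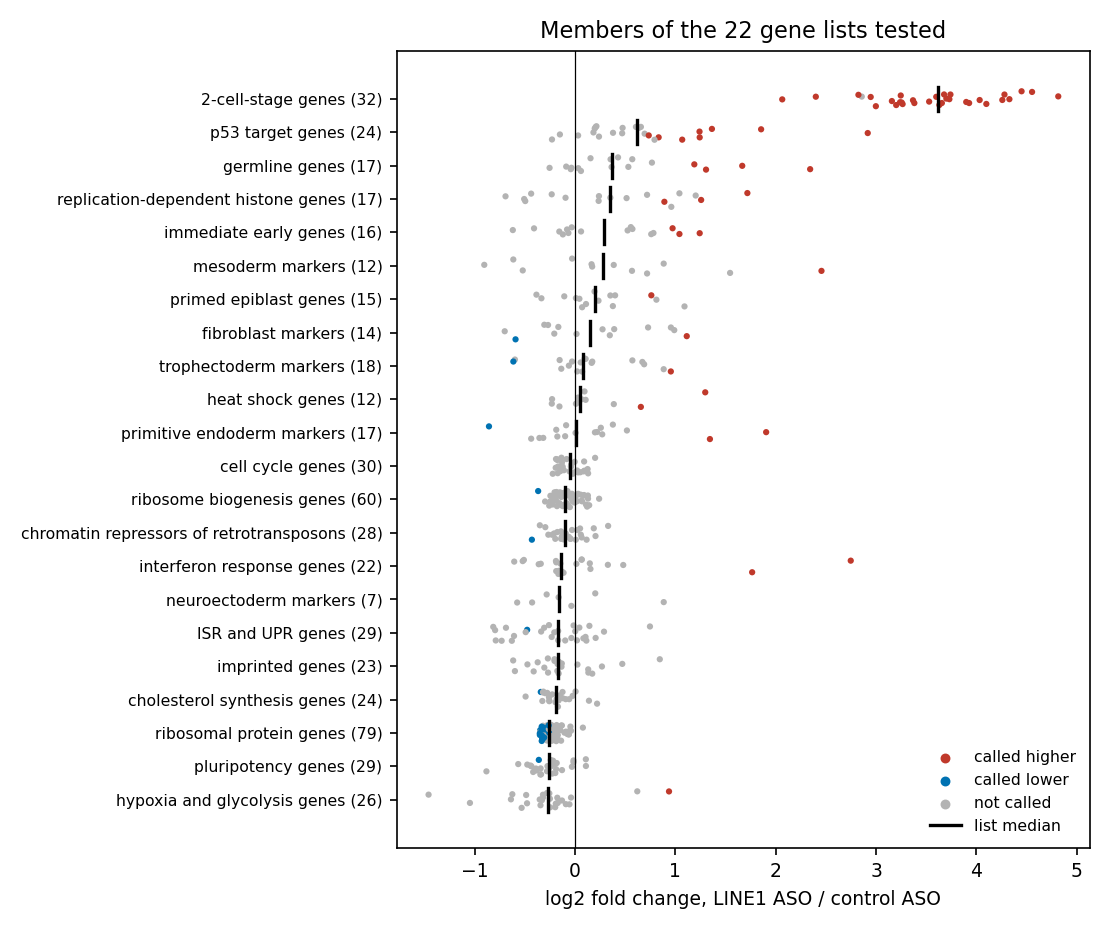
Log2 fold change (LINE1 ASO over control ASO) of the tested members of 22 gene lists, with the number tested in brackets, members called higher in red, called lower in blue and not called in grey, and a black bar at each list's median. The 2-cell-stage list stands apart at a median of 3.62, p53 targets follow at 0.62, and the ribosomal protein and pluripotency lists both lie at -0.26.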

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

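The settings that leave out both replicate 2 libraries, and the one-table fit with the replicate block, were chosen after the data were seen. The count of 899 called genes rose to 4964 with the replicate block and 1632 with DESeq2, and fell to 496 with a 2-fold minimum. It was 3039 without both replicate 2 libraries, and it ranged from 162 to 1519 when 1 library was left out. RLE factors, library totals, no filter and the CPM filter gave 758 to 1030. The share of calls that were higher went from 80.8% to 95.1% with library totals and 52.2% with the block. From 0 called repeats the count went to 9 with DESeq2, 1 without a filter (MT2_Mm), 3 with the repeat table's own scale (B2_Mm1a, B2_Mm1t and MMVL30-int) and 9 in one table with the genes. It was 58 without both replicate 2 libraries and 0 to 51 with 1 library left out. One table with the replicate block gave 133, of which 37 were higher and 96 lower, against 7 and 2 without the block. The 12 called lists became 0 with an estimated correlation and 4 with fry, and 8 to 13 with 1 library left out. The cause of these moves was not tested.

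The summed L1Md log2 ratio ranged from -0.49 to 0.044 with 1 library left out, and was negative under the other alternatives. The summed MERVL log2 ratio stayed between 1.97 and 2.72 under every alternative. L1Md_F turned to 0.012 with library totals or the repeat table's scale and L1Md_F3 to -0.020 with the replicate block and -0.034 in one table with it. With 1 library left out L1Md_F ranged from -0.28 to 0.10, L1Md_F2 from -0.33 to 0.11 and L1Md_F3 from -0.25 to 0.34. L1Md_Gf then ranged from -0.48 to 0.15, L1Md_T from -0.52 to 0.066 and L1Md_A from -0.53 to -0.021. Lists that were not called and turned direction were primed epiblast (adjusted p from 0.0638 to 0.907 with 1 library left out), heat shock (0.282 to 0.986) and neuroectoderm (0.783 without a filter). Of 58 called genes that the naming rule takes, 14 passed in all 6 fits that left out 1 library, and 43, 6 and 42 were lost without control replicate 1, 2 and 3 and 35, 7 and 33 without LINE1 ASO replicate 1, 2 and 3. None of the named genes changed direction, and library totals lost 11 calls. The replicate block ended no call of a named gene and, among the lists called by camera, only that of the immediate early genes, while all 4 fry calls were lost (adjusted p 0.0711 to 0.0765). The cell cycle list passed with no filter (0.0145). With 3 libraries per arm an exact test on 1 value cannot reach 0.05.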

Other observations

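Families of genes that share the letters opening their symbol were scanned after the data were seen, with 914 Fisher's exact tests over 457 families of at least 5 tested genes, of which 6 passed. Of 16 Wnt genes, which encode secreted signalling ligands, 8 were called higher (Benjamini-Hochberg adjusted p = 9.26e-05 from Fisher's exact test). In the control arm Wnt10b, Wnt9b, Wnt8b, Wnt10a and Wnt3a stood at 0.071, 0.138, 0.274, 0.275 and 0.539 CPM. The other members called higher, Wnt6, Wnt8a and Wnt9a, stood at 1.58, 3.82 and 4.11 CPM there. Wnt8b rose 5.45-fold, Wnt6 2.45-fold and Wnt9a from 4.11 ± 2.10 to 12.1 ± 1.99 CPM (SD, n = 3 each), genes picked after their values were seen. Of 37 genes whose symbol opens with Col, 10, all collagen chain genes, were called higher (adjusted p = 0.00189 by the same test), including Col15a1 (log2 fold change 2.63), Col6a4 (3.44-fold) and Col2a1 (2.11-fold). The other 4 were Zscan, with 6 of 15 higher (adjusted p = 0.00878 by the same Fisher's exact test), all of the Zscan4 cluster, and 3 with members lower. These were Rps (12 of 44, 6.55e-11), Rpl (10 of 48, 7.85e-08) and the septins (3 of 11, 0.0374), with Sept1 at a log2 fold change of -0.64. The 12 Rps genes include Rps6ka6, a kinase gene that is not a ribosomal protein gene. The family counts were not redone with libraries left out. Each test took all tested genes as background, of which 726 of 14725 were called higher, with no match on abundance. Under 1 CPM in the control arm were 39.4% of the genes called higher and 12.3% of those tested. A family result is therefore not separated from abundance. The fixed lists held 59 of the genes that rose and 29 of those that fell.

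The tests on shared reads, library scaling and repeat reads in general were chosen after the results they bear on were seen. The increase of 2-cell-stage genes was weighed first. For sequence shared with other annotated transcripts, the members with under 5% of their 50-base sequences in other genes were examined. All 5 of these tested members were called higher: Arg2, Lmx1a, Spz1, Tmem92 and Ubtfl1, with increases of 5.28-fold to 19.4-fold. Spz1, Ubtfl1 and Lmx1a stood at 0.042, 0.067 and 0.25 CPM in the control arm. The count filter thus kept them through the LINE1 ASO arm. As 31 of the 32 tested members of the list were called higher, the count among these 5 was largely fixed in advance. It cannot decide on shared reads and shows only that these 5 rose with little such sharing. Sequence shared with repeats or unannotated copies was not examined, and Dux had no value. The 26 members with more sharing are not covered. A single library does not account for the increase of the list: at least 18 members passed in each fit that left out 1 library, with list medians from 3.08 to 3.82. Other explanations stay open. An effect of the LINE1 ASO sequence on other targets is 1 of them, since 1 oligonucleotide was used per arm, and that was not tested. Chance is not ruled out either, as the splits of the libraries given below are too few.

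The decrease of ribosomal protein genes was weighed second. Neither library scaling nor transcript length, GC content and abundance can be ruled out. Within replicate numbers the list's own median log2 ratio was at most -0.16 under TMM, RLE or library totals, but these moved the median of all genes by only 0.10, too little to bring the list to 0. In the fit with the replicate block 0% of 10000 random sets matched on these properties reached the list median of -0.26, but the matched genes had a median log2 CPM of 8.51 against 9.31, so the match fell short. The bound set beforehand assumed a close match and is not applied, a requirement added after the result was seen, and 10 other genes of at least 512 CPM and under 2000 exonic bases had a median of -0.25 (-0.44 to 0.09).

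The lower L1Md reads within replicate numbers were weighed last. They may be part of a decrease of abundant repeat reads in general: in one table with the replicate block, 66.3% of 10000 random sets of 6 other repeats of like abundance had a median as low as the L1Md median of -0.17. The sets had a median of -0.19 and a 2.5 percentile of -0.275. This test weighs the 6 L1Md repeats alike, so it does not test their summed reads. L1Md_A and L1Md_T, the most abundant of them, stood at -0.26 and -0.25 in the same fit. A loss specific to the targeted family is therefore not separated from a decrease that it shares with other repeats.

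The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 899 genes and the highest other split 0, with 1 of 10 as large as the real one. For lists the real split called 12 and the highest other 10, again 1 of 10. Each split that mixes the arms called lists by the preset test, so passing it does not by itself mark a difference between the arms. For repeats the real split called 0 and the highest other 0, so 10 of 10 were as large. Among the 4 splits that part all 3 pairs, the other 3 called 0 genes and 4 to 9 lists, and each of them mixes the arms.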
